A study of Arabidopsis thaliana with 4 samples.

How the data were processed

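PolyA-selected mRNA of 4 seedling samples was sequenced, 2 labelled Col-0 (wild type replicates 1 and 2) and 2 labelled MAC3B Q77A/D81A-GFP (mutant replicates 1 and 3). The column names of the count table number the wild-type libraries differently, and the sample descriptions in the labels tie each column to its sample. Raw counts per gene were deposited, made per the file headers with featureCounts 2.0.1 on paired reads over exons of the Ensembl Plants TAIR10 annotation and with no strand option. Per the submitters' processing notes the tools used were HISAT2 2.2.0, STAR 2.7.9a, featureCounts 2.0.1 and DESeq2 1.30.1 with the TAIR10 build. Which aligner made which file and the rMATS version are not given in the sources used here. Exon length per gene was deposited with the counts and is an other kind of value that no test used.

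The authors' DESeq2 table was deposited with the mean of counts scaled by size factors (a signal), the log2 fold change with its error, the Wald statistic (a score) and the p-value and adjusted p-value per gene. The table of retained introns was deposited by the authors as rMATS output with p-values and false discovery rates, a difference of inclusion level between the numbered groups (a score from -1 to 1), effective lengths, and cells that join other values (read counts and inclusion levels) of 2 libraries per group. It names neither genotype, so no direction by genotype is given from it. A further deposited table holds an intron score in 4 columns named by genotype and number. Its making is not stated, and the values show it to be a coverage signal: score times intron length is a whole multiple of 1 factor per column for 99.9868% to 100% of introns above 0 (within 0.02), with factors of 12.9, 12.5, 12.7 and 10.1. The authors also deposited the mean of log2(score + 1) per genotype and the difference on the log2 scale, with a further sheet of the introns that differ by at least 4. Another 8 columns with single values of log2(score + 1) were not used here.

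Library totals were 23436163 and 24245300 counts in wild type and 23936296 and 30105517 in the mutant, so that 3 counts, used as the floor for a gene at 0, equal 0.0996 to 0.128 CPM. Floors cover counting error only. Counts of 32833 genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (20483 genes), normalized with TMM and tested with glmQLFit and glmQLFTest, with genotype as the only term, all 4 libraries in the fit and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.0971. CPM values and fold changes are from this fit. The gene lists were tested with camera on log CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 19 lists, and with fry from limma 3.58.1. Intron scores were tested with limma (eBayes with trend) on log2(score + 1) for introns above 0 in at least 1 column. The plan had assumed that the score was a ratio with a pseudocount of 0.01, and the pseudocount of 1 was taken once the unit was seen. Overlap, intron properties and closing tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Intron sequence came from the RefSeq copy of the TAIR10 genome after 99.6% of event introns and 98.2% of 1000 sampled score introns were checked to start with GT or GC and end with AG there. Gene symbols and products came from that annotation.

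On simulated counts with 200 changed genes among 20483, edgeR recovered 59.7% of genes changed 1.5-fold, 71.6% changed 2-fold and 86.4% changed 4-fold, with 9 false calls among 154. The simulated spread followed the trend with abundance and was alike in both genotypes. The real mutant libraries lay farther apart than the wild-type libraries, so recovery and false calls in the real data may differ. On simulated intron scores limma recovered at most 1.52% of introns shifted by 1 to 4 on the log2 scale, with 0 false calls.

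Named genes followed a rule fixed before the data were examined. It took MAC3B and MAC3A, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and separated libraries, and up to 3 members of each list past the threshold by size of change or, with none, the member with the smallest p. For introns it took the 6 largest increases and 4 largest decreases past the threshold with separated groups, and up to 2 introns per list. The limit of at least 20 reads in every library for the 6 and 4 was added after seeing the data. The numbered groups took the place of the genotypes, which are not named there. Exons of 18 of the 80 genes checked, the named ones and those of the closing section, share bases with another gene, mostly on the other strand, and the larger overlaps are given with the genes.

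Alternatives tried were RLE size factors, library totals, DESeq2 1.42.0, other filters on low counts, no organelle genes, a minimum fold change, each library left out in turn (where the genotype left with a single library is assumed to vary like the other), camera with an estimated correlation, fry, other pseudocounts, other sets of introns, other read minimums and one intron per gene. A test of inclusion and skipping counts by genotype, planned as the main intron test, was left out because the table does not name its groups, and the authors' false discovery rate is reported in its place. For gene expression the splits of samples were not counted for chance because each genotype has 2 libraries. For introns that differ by at least 4, the pairings of score columns that mix the genotypes were counted.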

Results

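The data were gene counts and intron measurements from polyA-selected mRNA of whole 7-day-old Arabidopsis thaliana seedlings, grown on Murashige and Skoog medium with sucrose and not treated. The wild type was the accession Col-0, with 2 libraries (replicates 1 and 2). The other 2 libraries (replicates 1 and 3) came from seedlings labelled MAC3B Q77A/D81A-GFP, called the mutant here, which carry a GFP-tagged MAC3B with both substitutions in its name. MAC3B is a plant homologue of yeast Prp19, a U-box ubiquitin ligase of the MOS4-associated complex, which works with the spliceosome. The wild-type libraries held 23436163 and 24245300 counted fragments and the mutant libraries held 23936296 and 30105517. The labels do not say whether the libraries of a genotype came from separately grown seedlings, so each p-value measures only the spread between these 4 samples.

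Expression is given in CPM, the counts scaled to a common library total. The first principal component of log2 CPM held 48.1% of the variance and separated the genotypes. Both wild-type libraries lay at -26.3 on it, while mutant replicate 1 lay at 39.3 and mutant replicate 3 at 13.4. The mutant libraries were also farther apart from each other than the wild-type libraries, with a chi-square per gene of 10.8 against 4.50. Chloroplast and mitochondrial genes took 0.0280% to 0.0435% of the counts, and the 10 most abundant genes took 7.19% to 8.39%.

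MAC3B itself (AT2G33340, chromosome 2, 14126141 to 14131224 of TAIR10) was at 156 and 162 CPM in the wild-type libraries and at 1147 and 947 CPM in mutant replicates 1 and 3. Its transcript rose 6.59-fold, a log2 fold change of 2.72 with a standard error (SE) of 0.0871 and n = 2 per genotype (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.41e-15). Its close homologue MAC3A (AT1G04510) was at 57.6 and 58.9 CPM in wild type and 58.0 and 59.7 CPM in the mutant, a log2 fold change of 0.01 with an SE of 0.0877 (edgeR, Benjamini-Hochberg adjusted p = 0.965). Gene counts do not separate transcripts of the transgene from those of the endogenous MAC3B locus. No line with an unmutated MAC3B-GFP is among the 4 samples, so the substitutions and the higher MAC3B level cannot be compared apart from each other. The labels do not give the genetic background of the transgenic line, so whether endogenous MAC3A or MAC3B function also differs between the genotypes is not known here.

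Between the genotypes, 617 of 20483 tested genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, of which 345 were higher and 272 lower in the mutant. Most changes were small, with a median absolute log2 fold change of 0.50 among these genes. At least a 2-fold change was seen for 88 of the higher and 20 of the lower genes. The excess of higher genes depended on the scaling, since library totals alone gave 507 higher and 194 lower genes, or 72.3% higher against 55.9%. The number of genes depended on each library, with 135 genes called without wild type replicate 1, 220 without wild type replicate 2, 1006 without mutant replicate 1 and 1848 without mutant replicate 3. In the fits without a mutant library the spread came from the wild-type pair alone, which lay closer together than the mutant pair.

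The most raised transcript of moderate abundance was AT1G63530 (chromosome 1, 23563315 to 23565586), at 5.20 ± 0.559 CPM in wild type and 107 ± 21.5 CPM in the mutant (mean ± SD, n = 2). AT1G59660 (chromosome 1, 21923986 to 21929437), which encodes a nucleoporin of the autopeptidase family, rose 16.0-fold from 8.20 ± 2.1 to 131 ± 1.68 CPM. AT5G46070, a guanylate-binding protein gene on chromosome 5 (18683319 to 18688822), rose 14.2-fold from 73.8 ± 2.69 to 1049 ± 76.5 CPM. Its upstream neighbour AT5G46060 rose 6.30-fold, from 1.47 ± 0.128 to 9.26 ± 0.357 CPM. AT1G69680, a gene of the Mog1 family of Ran-binding proteins, rose 6.35-fold from 6.85 ± 0.896 to 43.5 ± 2.00 CPM. The RNA-recognition gene AT1G72800 rose 9.46-fold and the RING-type zinc finger gene AT5G60250 rose 8.73-fold. The counting did not use strand, and 44.2% of the exon bases of AT1G72800 and 12.8% of those of AT5G60250 overlap a gene on the other strand, so the source of their reads is uncertain. Adjusted p-values of these 7 genes ran from 1.80e-17 for AT5G46070 to 2.37e-06 for AT5G60250 (edgeR, Benjamini-Hochberg), and all 7 kept their call without any 1 library. The log2 fold change of AT5G60250 was 3.13, and 3.77 without wild type replicate 1.

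Among transcripts of moderate abundance the strongest loss was that of AT1G67105, a noncoding RNA gene on chromosome 1 (25057479 to 25058264), which dropped 46.1-fold from 81.5 ± 1.08 CPM in wild type to 1.79 ± 0.384 CPM in the mutant (mean ± SD, n = 2). The ribosomal protein gene AT1G08360 (chromosome 1, 2635939 to 2638004) dropped 17.9-fold, from 177 ± 11.1 to 9.88 ± 0.800 CPM. The lectin-family gene AT5G35940 dropped 2.99-fold, from 24.3 ± 0.739 to 8.08 ± 1.42 CPM. The microRNA gene MIR167d dropped 2.38-fold, AT3G46370 2.15-fold and AT4G22755 2.12-fold. The leucine-rich repeat gene AT2G15880 fell from 155 ± 6.81 to 79.4 ± 0.970 CPM, and the thioredoxin-family gene AT4G15690 from 8.79 ± 0.0765 to 4.60 ± 0.645 CPM. Adjusted p-values of the 8 genes ran from 9.88e-17 for AT1G08360 to 0.0336 for AT3G46370 (edgeR, Benjamini-Hochberg). Without wild type replicate 2 the calls of MIR167d (adjusted p = 0.149), AT3G46370 (0.573), AT4G22755 (0.175) and AT4G15690 (0.140) were lost, as were those of AT4G22755 (0.107) and AT4G15690 (0.168) without wild type replicate 1 (edgeR, Benjamini-Hochberg).

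**Figure D1:**
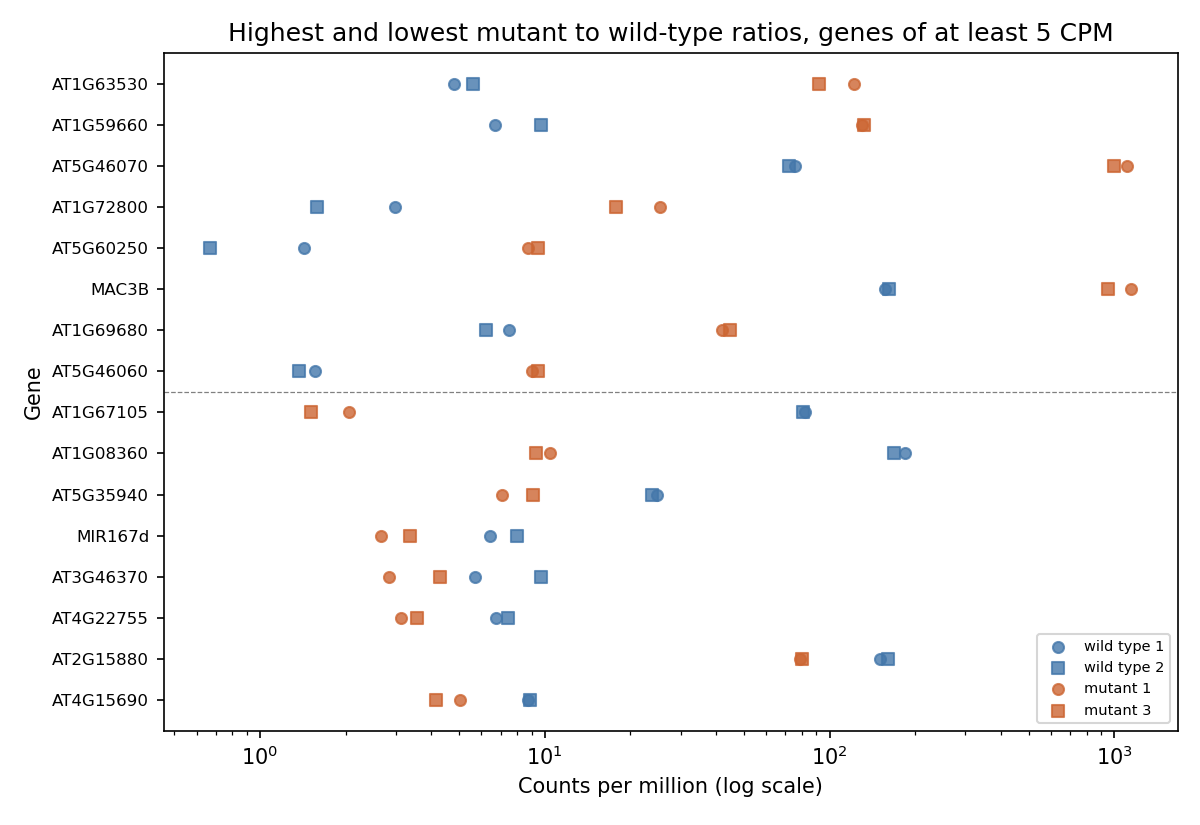
Expression in CPM on a log scale (horizontal axis) of the 8 genes with the highest and the 8 with the lowest mutant to wild-type ratios among genes past the threshold with a mean of at least 5 CPM (vertical axis). Each point is 1 library, and both mutant libraries lie on the same side of both wild-type libraries, as the rule for naming these genes required.

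Gene groups were followed with 19 lists fixed before the data were examined, of which 388 of 432 genes were tested. With a preset inter-gene correlation of 0.01, camera placed 6 lists higher and 2 lower in the mutant at a Benjamini-Hochberg adjusted p under 0.05. With camera estimating the correlation from these 4 libraries 0 of the 19 passed, 1 having an unadjusted p under 0.05. That version has only the residual degrees of freedom of the 4 libraries and so little power. Its misses do not show that correlation between genes accounts for the results. Of the lists that passed with the preset value, DNA damage and flowering time had estimated correlations of -0.13 and -0.01. The others had estimates above the preset 0.01. These were 0.40 for iron homeostasis, 0.34 for photosynthesis, 0.28 for glucosinolates, 0.16 for abscisic acid, 0.05 for salicylic acid and 0.02 for auxin. Correlation between genes therefore stays open for these lists. Fry passed 1 list for change in one direction, DNA damage, and 7 for change in either direction. These 7 were the DNA damage, abscisic acid, circadian clock, root marker, cell division, MAC complex (with MAC3B itself among its members) and microRNA target lists.

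Genes of the DNA damage response were higher as a group, with positive values for all 8 tested members and a median log2 fold change of 0.66. Of the 8, 3 rose over all genes tested and 5 adjusted over the list alone. GMI1, a cohesin-related repair gene, had a log2 fold change of 1.29 (SE 0.189, n = 2 per genotype), the recombination repair gene BRCA1 0.73 (SE 0.196) and the ribonucleotide reductase gene TSO2 0.58 (SE 0.0942). The other 5 members, the cell cycle inhibitor SMR7 at 1.17 (SE 0.624) among them, did not pass. The list gave an adjusted p of 8.41e-06 by camera with Benjamini-Hochberg, adjusted p = 0.436 with an estimated correlation, and 0.0164 by fry. Without wild type replicate 1 the calls of BRCA1 (adjusted p = 0.107) and TSO2 (0.0625) were lost, and that of BRCA1 also without wild type replicate 2 (0.446) and mutant replicate 1 (0.0787), in edgeR with Benjamini-Hochberg. BRCA1 also missed the threshold in DESeq2 (Benjamini-Hochberg adjusted p = 0.0601).

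Glucosinolate synthesis genes were also higher, 15 of 16 members having positive values with a median log2 fold change of 0.33. Over all genes tested 4 of them rose, and 13 adjusted over the list alone. The cytochrome P450 genes CYP79F1 and CYP83A1, which act early in the aliphatic branch, had log2 fold changes of 0.96 (SE 0.163) and 0.93 (SE 0.10), and their transcriptional activator MYB29 0.94 (SE 0.247). The fourth, CYP79B2 of the indolic branch, named after its value was seen, was at 0.32 (SE 0.0862). CYP79F1 and its tandem copy CYP79F2 (0.41) may share reads, so the split between them is uncertain. The list gave an adjusted p of 8.41e-06 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation. Without wild type replicate 1 the calls of CYP79F1 (adjusted p = 0.0543) and MYB29 (0.372) were lost, and that of MYB29 also without wild type replicate 2 (0.102) and mutant replicate 3 (0.127), in edgeR with Benjamini-Hochberg.

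The list of abscisic acid, cold and drought genes had 5 of 25 members higher over all genes tested and 6 adjusted over the list alone. The late-embryogenesis protein gene LEA4-5 rose by 1.79 on the log2 scale (SE 0.335, n = 2 per genotype), the caleosin gene RD20 by 1.54 (SE 0.350) and the cold-induced KIN2 by 0.87 (SE 0.183). The remaining pair, named after their values were seen, was RD29A at 0.82 (SE 0.137) and RD22 at 0.38 (SE 0.0832). Other members, such as the cold regulator CBF3 at -2.17 (SE 0.915), did not pass. The list had an adjusted p of 0.000428 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation. The calls of RD20 (adjusted p = 0.185) and KIN2 (0.248) were lost without wild type replicate 1, and that of RD20 without wild type replicate 2 (0.0606), in edgeR with Benjamini-Hochberg. KIN2 also missed the threshold in DESeq2 (Benjamini-Hochberg adjusted p = 0.306).

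Among salicylic acid and immune genes 2 of 24 rose, both over all genes and adjusted over the list alone. They were CYP71A13, with a log2 fold change of 2.31 (SE 0.553) at 0.468 CPM in wild type and 2.35 CPM in the mutant, and PAD3 at 0.68 (SE 0.173), which both encode enzymes of camalexin synthesis. The list had an adjusted p of 0.00357 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation. CYP71A13 shares 22.1% of its exon bases with a gene on the other strand. Both calls depended on single libraries: without wild type replicate 1, wild type replicate 2 and mutant replicate 1 the adjusted p was 0.149, 0.172 and 0.262 for CYP71A13 and 0.0604, 0.424 and 0.0670 for PAD3 (edgeR, Benjamini-Hochberg).

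Iron homeostasis genes had 2 of 17 members higher over all genes and 3 adjusted over the list alone. The neighbouring iron-deficiency regulators BHLH38 and BHLH39 had log2 fold changes of 1.33 (SE 0.257) and 0.93 (SE 0.20). Mutant replicate 3 was highest for both, at 13.3 CPM of BHLH38 against 7.16 in mutant replicate 1 and 3.97 to 4.24 in wild type. BHLH38 shares 35.7% of its exon bases with PIP5K4 on the other strand, so the source of its reads is uncertain. Of their possible targets in root iron uptake, IRT1 was at 0.00 (SE 0.352) and FRO2 at -0.06 (SE 0.241). The list had an adjusted p of 0.0219 by camera with Benjamini-Hochberg and adjusted p = 0.551 with an estimated correlation, and was lost without wild type replicate 1 (0.145) and without mutant replicate 3 (0.610). Without mutant replicate 3 the calls of BHLH38 (adjusted p = 0.0614) and BHLH39 (0.112) were lost as well, and that of BHLH39 without wild type replicate 1 (0.124), in edgeR with Benjamini-Hochberg.

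For auxin response and lateral root genes 2 of 25 rose over all genes and 5 adjusted over the list alone. The auxin-induced repressor gene IAA1 had a log2 fold change of 0.60 (SE 0.152) and the auxin conjugase gene GH3.5 one of 0.33 (SE 0.0797). The list had an adjusted p of 0.0359 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation, and was lost without wild type replicate 1 (0.289) and without mutant replicate 3 (0.251). Both genes lost their calls without wild type replicate 1 (adjusted p = 0.247 for IAA1 and 0.425 for GH3.5) and without wild type replicate 2 (0.232 and 0.210), and IAA1 also without mutant replicate 3 (0.0678), in edgeR with Benjamini-Hochberg.

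Nuclear genes of photosynthesis were lower as a group by a small amount, with negative values for 27 of 31 members and a median log2 fold change of -0.20. Over all genes tested 9 fell and 1 rose, and 19 fell and 2 rose adjusted over the list alone. The protochlorophyllide reductase gene PORB fell by 0.53 (SE 0.0684, n = 2 per genotype), from 681 ± 4.57 to 473 ± 8.99 CPM, and the light-harvesting gene LHCB1.4 fell by 0.45 (SE 0.110). The Rubisco small subunit gene RBCS1B rose by 0.72 (SE 0.0872), from 231 ± 30.01 to 380 ± 34.6 CPM. LHCB1.4 and RBCS1B belong to families of near-identical copies (RBCS2B at -0.15 and RBCS3B at -0.27 lie beside RBCS1B), so reads may be split between copies and single-copy values are uncertain. The list had an adjusted p of 6.61e-05 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation. LHCB1.4 lost its call in DESeq2 (adjusted p = 0.537) and, in edgeR, without wild type replicates 1 (0.253) and 2 (0.285), all with Benjamini-Hochberg.

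Flowering time genes were lower as a group, with negative values for 13 of 15 tested members and a median log2 fold change of -0.24. Of these, 2 fell, over all genes and adjusted over the list alone: the floral integrator SOC1 by 0.72 (SE 0.171) and the RNA-binding regulator FCA by 0.41 (SE 0.0995). SOC1 and FCA both promote flowering, but the list mixes promoters with repressors, and the repressors MAF2 (-0.25), FLM (-0.24), MAF3 (-0.24) and MAF4 (-0.62) also had negative values and did not pass. The list had an adjusted p of 0.00517 by camera with Benjamini-Hochberg and adjusted p = 0.436 with an estimated correlation. Without wild type replicate 1 the adjusted p was 0.325 for SOC1 and 0.349 for FCA, without mutant replicate 1 it was 0.0605 and 0.0633, and without wild type replicate 2 it was 0.121 for FCA (edgeR, Benjamini-Hochberg).

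The circadian clock list did not pass the test as a whole (camera, Benjamini-Hochberg adjusted p = 0.463) but passed fry for change in either direction (Benjamini-Hochberg adjusted p = 0.00399), and 4 of its 25 members changed, and 5 adjusted over the list alone. The dawn-expressed regulators LHY and CCA1 rose by 1.00 (SE 0.127) and 0.91 (SE 0.0960) on the log2 scale, and the related RVE8 by 0.56 (SE 0.137). LHY was at 17.0 and 15.9 CPM in wild type and 36.2 and 29.7 CPM in the mutant. PRR7, a repressor of CCA1 and LHY, named after its value was seen, fell by 0.44 (SE 0.0716). RVE8 lost its call without wild type replicates 1 (adjusted p = 0.201) and 2 (0.231), and PRR7 without wild type replicate 1 (0.0857), in edgeR with Benjamini-Hochberg.

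In the heat shock list 2 of 12 members rose over all genes and 3 adjusted over the list alone. The chaperone gene HSP70-4 rose 2.62-fold, from 27.1 ± 7.54 to 71.3 ± 13.3 CPM (mean ± SD, n = 2), and HSP90.1 rose 1.92-fold, from 13.5 ± 1.58 to 25.9 ± 1.42 CPM. The list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0676), and passed it without wild type replicate 2 (0.000756). The flavonoid list had 1 of 10 members higher, the chalcone synthase gene CHS at 0.54 (SE 0.108), and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.136). CHS lost its call without wild type replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.238).

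The question of whether the spliceosome itself shifted was followed with the MAC complex and splicing factor lists. MAC3B was the only 1 of 16 tested MAC complex members past the threshold. The list did not pass camera (Benjamini-Hochberg adjusted p = 0.136) and passed fry for change in either direction (0.0118). MAC3B, which the transgene encodes, is in the list and no test without it was run. The fry result therefore does not show a shift of the other members. Its median log2 fold change was 0.02 and its mean 0.28. Of 41 other splicing factor genes, the serine/arginine-rich factors RS31A (1.11, SE 0.233) and RSZ22A (0.45, SE 0.115) rose and the glycine-rich RNA-binding protein gene GRP7 fell by 0.47 (SE 0.105), the same 3 as adjusted over the list alone. The splicing factor list had a median of -0.03 and a mean of 0.04, with an adjusted p of 0.972 by camera with Benjamini-Hochberg in the lower direction. Exons of RS31A overlap a gene on the other strand over 27.2% of their bases. All 3 genes lost their calls without wild type replicate 1 (adjusted p = 0.236 for RS31A, 0.485 for RSZ22A and 0.156 for GRP7), and RSZ22A (0.0755) and GRP7 (0.0878) also without wild type replicate 2 in edgeR and (0.0509 and 0.372) in DESeq2, all with Benjamini-Hochberg.

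Genes of microRNA biogenesis, a process that MAC3 proteins are known to affect, showed no call in edgeR over all genes or adjusted over the list alone (0 of 14, with 2 at an unadjusted p under 0.05 and 0 in DESeq2; camera, Benjamini-Hochberg adjusted p = 0.972). The smallest p belonged to the uridylyltransferase gene HESO1 at a log2 fold change of 0.40 (SE 0.152), with an unadjusted p of 0.0166 in edgeR and Benjamini-Hochberg adjusted p-values of 0.198 in edgeR and 0.313 in DESeq2. HESO1 passed without mutant replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0271) and shares 12.8% of its exon bases with a gene on the other strand. Among 56 microRNA target genes 1 rose, the phosphate regulator PHO2 at 0.40 (SE 0.0816). The target list had a median of 0.01 and a mean of 0.03, with the lower direction in camera (Benjamini-Hochberg adjusted p = 0.972), and passed fry for change in either direction (0.0376). PHO2 lost its call without wild type replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.426).

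Markers of the seedlings' tissues were followed as a check on tissue make-up, and none of these lists passed camera with Benjamini-Hochberg. The root tissue markers (adjusted p = 0.00354) and the cell division genes (0.0390) passed fry for change in either direction with Benjamini-Hochberg, and the shoot (0.0541) and seed (0.731) markers did not. Of 22 root tissue markers 2 rose, the Casparian strip genes CASP5 at 0.58 (SE 0.149) and CASP2 at 0.49 (SE 0.127), with an adjusted p of 0.230 for the list. Of 12 markers of the shoot meristem, leaf primordium and stomatal lineage 1 rose, the meristem homeobox gene KNAT1 at 0.85 (SE 0.157), with an adjusted p of 0.205. Of 5 seed storage and embryo markers 0 passed edgeR over all genes, 1 had an unadjusted p under 0.05, and DESeq2 gave none an adjusted p. ABI3 was nearest, at 3.99 CPM in mutant replicate 1, 0.856 in mutant replicate 3 and 0.459 to 0.692 in wild type (unadjusted p = 0.00424, edgeR adjusted p = 0.0901), and it passed adjusted over the list alone. The seed list had an adjusted p of 0.213, and 6.00e-05 without wild type replicate 2, and ABI3 one of 5.36e-05 without mutant replicate 3. Of 14 cell division genes 0 passed edgeR or DESeq2 and 3 had an unadjusted p under 0.05 in edgeR (list adjusted p = 0.136), the cytokinesis gene KNOLLE being nearest at -0.35 (SE 0.112; unadjusted p = 0.00576, adjusted p = 0.108 in edgeR and 0.179 in DESeq2). KNOLLE shares 33.5% of its exon bases with NPQ1 on the other strand. Without wild type replicate 1 the calls of CASP5 (adjusted p = 0.357), CASP2 (0.277) and KNAT1 (0.141) were lost, those of CASP5 (0.161) and CASP2 (0.270) also without wild type replicate 2, that of CASP5 without mutant replicate 1 (0.0631), and that of CASP2 without mutant replicate 3 (0.103) and in DESeq2 (0.0570), all with Benjamini-Hochberg.

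**Figure D2:**
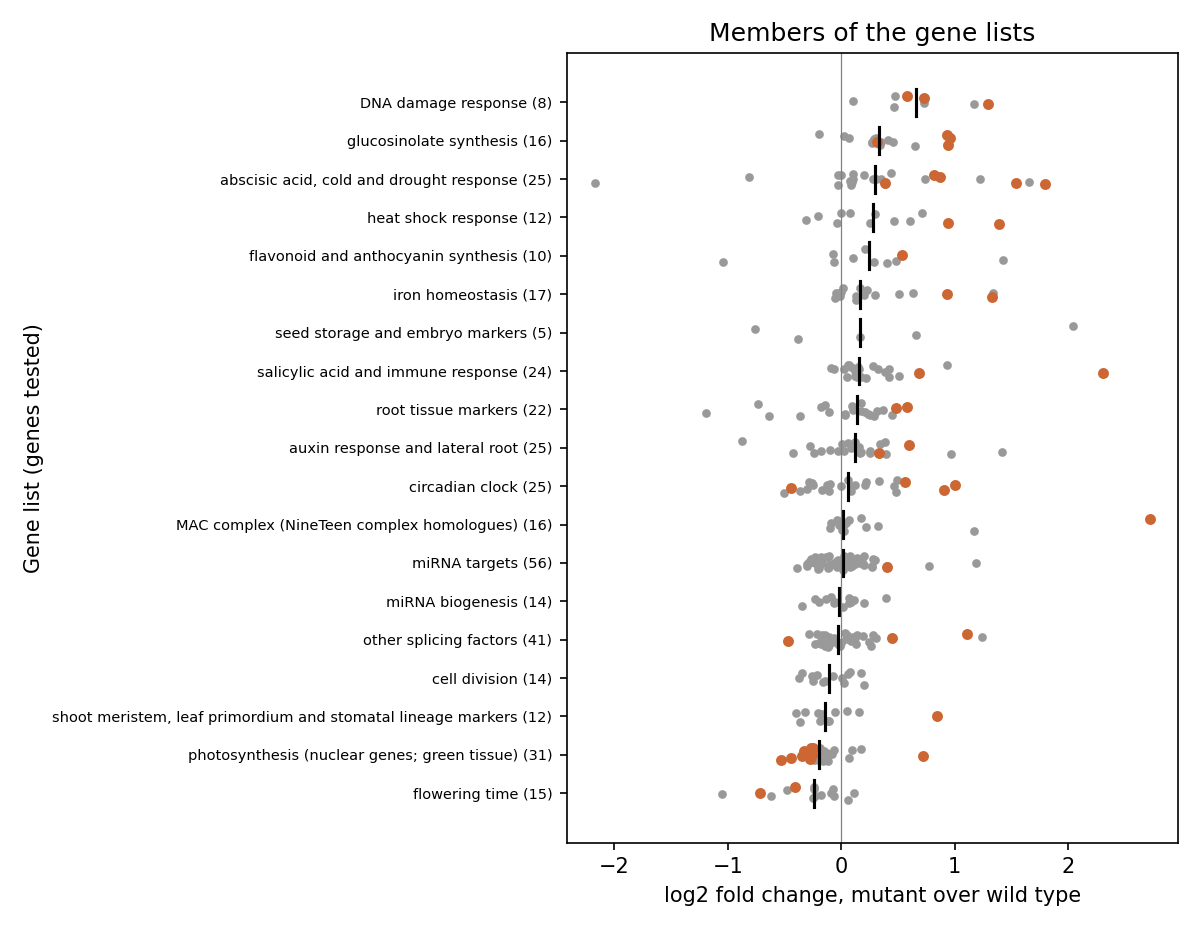
Log2 fold changes, mutant over wild type (horizontal axis), of the tested members of the 19 gene lists (vertical axis, with the number of genes tested). Orange points passed the edgeR test over all genes, grey points did not, and black bars mark the list medians, from 0.66 for the DNA damage response to -0.24 for flowering time.

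Intron retention, the question that a change in a spliceosome-associated ligase raises, was given in the authors' deposited table of an rMATS comparison, in which the 2 groups are numbered and not named by genotype. Values are therefore given by group number. Per the authors' deposited table, 774 of 4690 retained-intron events (16.5%), in 699 genes, had a false discovery rate under 0.05, 365 with more retention in group 1 and 409 with more in group 2. The median absolute difference of inclusion level among them was 0.123. Among events of the authors' deposited table past that rate, with group values that did not overlap and at least 20 reads in every library, the largest differences toward group 1 were in AT3G21755 (chromosome 3, 7667044 to 7667123, 46.3 percentage points), AT4G27270 (41.7), AT3G07760 (41.0), a pair of introns of AT1G09195 (35.5 and 33.2) and the phosphate transporter gene PHT4;3 (32.7). The largest toward group 2 under the same limits in the authors' deposited table were -50.6 percentage points in AT5G66558 (chromosome 5, 26564384 to 26564530), -48.1 in AT1G13650, -41.9 in AT1G16930 and -41.5 in AT5G65740.

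Among splicing factors 7 of 33 events, in 4 genes, passed the false discovery rate in the authors' deposited table, and among flowering time genes 4 of 10 events, in 4 genes, with 16.5% of all events past it. The 705-base intron of RS31A (chromosome 2, 19137682 to 19138386) differed by -30.1 percentage points (false discovery rate 0.0161), and an intron of SR34A by 8.5. For the clock genes the authors' deposited table listed PRR3 at 21.6 and LNK1 at -3.5, the former on a mean of 7.25 reads per library. For flowering genes it listed MAF4 at 19.6 and MAF2 at -1.9, for microRNA targets SNZ at 15.3 and MYB33 at 9.6, and for cell division AUR2 at 21.3 percentage points in the authors' deposited table. The MAC complex list had 0 of 2 events past the false discovery rate there.

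Genes with such an intron did not differ detectably in expression calls from the other genes with an event. The comparison covered the 3129 genes with an event that were also tested for expression. Of the 692 among them with an event past the false discovery rate in the authors' deposited table, 10 were higher in the mutant, against 25 of 2437 others (odds ratio 1.41, p = 0.411, two-sided Fisher's exact test). For lower genes the counts were 14 and 37 (odds ratio 1.34, p = 0.394, two-sided Fisher's exact test). The introns past that rate had a median length of 105.5 bases against 108 for the others, a GC content of 33.7% in both, and a position along the gene at 58.1% against 57.0% from its 5′ end. Adjusted over the 4 properties tested with Benjamini-Hochberg, mean reads included, each p was 0.845 (two-sided permutation tests with 100000 resamples; unadjusted p = 0.452 for length, 0.845 for GC content, 0.683 for position and 0.517 for reads). Introns are not independent replicates.

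A separate deposited table gave a coverage score for 79373 introns in 2 wild-type and 2 mutant columns, whose names tie them to genotypes but not to single libraries. By coordinates 0 introns were shared with the rMATS events, so the score tests did not measure the introns of those events. The lowest p belonged to an intron of AT5G46070, a gene that rose in expression. The intron at 18686982 to 18687066 on chromosome 5 had scores of 23.4 and 69.5 in the wild-type columns and 3558 and 2769 in the mutant columns. Limma on log2(score + 1) called 0 higher and 0 lower introns of the 41390 above 0 in at least 1 column (lowest Benjamini-Hochberg adjusted p = 0.187, for that intron). An unadjusted p under 0.05 was reached by 739 introns, with 2069.5 expected by chance. That number depended on the pseudocount. It was 1105 with a pseudocount of 0.1, 2405 with the planned 0.01 and 3058 with 0.001. Limma called 0 introns with each of them (lowest Benjamini-Hochberg adjusted p = 0.661, 0.662 and 0.494). With simulated shifts of 4 on the log2 scale limma recovered 0 of 66 changed introns, so this test over all 41390 introns had little power for changes of that size. Shifted introns were drawn at random, and each intron's spread was taken from its own 2 columns per genotype. The simulation therefore does not describe single well-covered introns. Leaving out mutant column 1 gave 7331 higher and 25 lower introns, and leaving out any other column gave 0. The mutant side of that fit was column 2 alone, without a replicate, and it was the deepest column, with 35.5% of introns above 0 against 27.7% to 29.9% in the others.

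Among the 10788 introns with scores above 0 in all 4 columns, a choice made after seeing the data, limma called 2 higher and 2 lower introns. Each lay in a gene whose expression had changed in the same direction. The intron of AT5G46070 differed by 6.24 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 4.63e-05; gene log2 fold change 3.83), and an intron of RAN-1, which encodes the Ran GTPase, by 2.305 (0.0269; gene 1.81). An intron of AT2G15880 differed by -1.15 (limma, Benjamini-Hochberg adjusted p = 0.0269; gene -0.97) and one of GRP7 by -0.60 (0.0288; gene -0.47). Relative to the expression of each intron's gene, limma called 0 introns (lowest Benjamini-Hochberg adjusted p = 0.947; 524 at an unadjusted p under 0.05, with 535.3 expected by chance). The median log2(score + 1) was 5.98 ± 0.00889 in wild type and 6.04 ± 0.050 in the mutant (mean ± SD of column medians, n = 2), a difference of 0.07. The exact permutation test, two-sided, gave p = 0.333, the smallest that 2 against 2 columns allow.

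A difference of at least 4 on that scale was shown by 2336 introns, 1417 higher and 919 lower in the mutant. Other pairings of the same 4 columns, each with 1 column of both genotypes on either side, gave 2234 and 2276 such introns. In each of the 3 pairings more introns were higher on the side that held mutant column 2, the deepest column, with 1371 against 863 and 1478 against 798 in the mixed pairings. Among introns above 0 in all 4 columns, 18 were higher and 19 lower in the mutant. Of the 2336, 98.4% were listed at 0 in at least 1 column and 1771 in both columns of 1 genotype. The 2336 included introns of the raised genes AT5G46070, AT1G69680, AT1G63530 and AT1G59660, such as the AT5G46070 intron at 18687145 to 18687314, listed at 0 in both wild-type columns and at 942 and 704 in the mutant columns. No intron of MAC3B, whose transcript also rose, was among them. The largest difference of a MAC3B intron was 2.36.

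**Figure D3:**
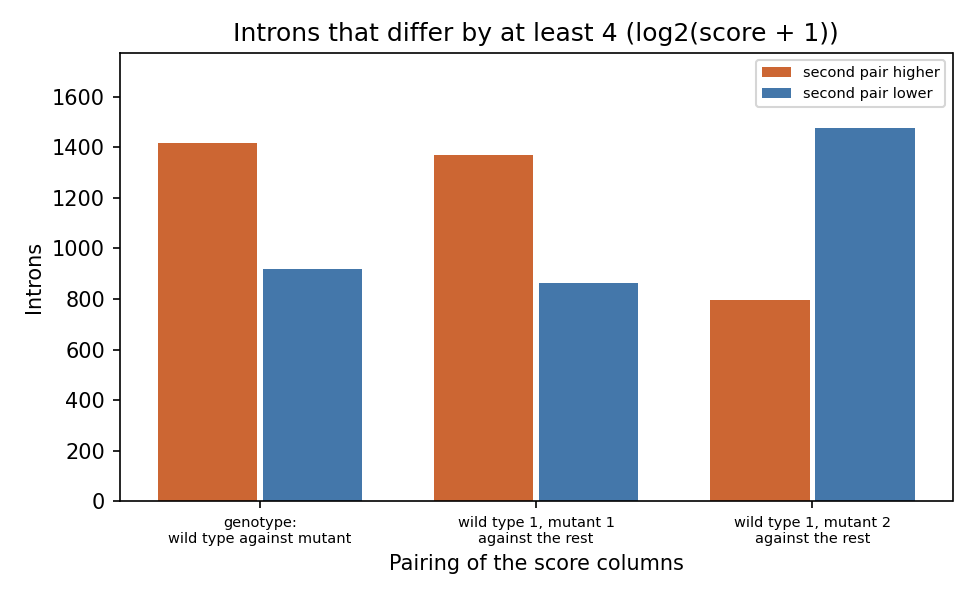
Number of introns (vertical axis) whose mean log2(score + 1) differs by at least 4 between a first and a second pair of score columns, for the genotype pairing and for both pairings that mix the genotypes (horizontal axis). Bars count introns higher or lower in the second pair, and the 3 pairings total 2336, 2234 and 2276 introns.

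Per the authors' deposited table of DESeq2 results, 510 genes had an adjusted p under 0.05, 264 with positive and 246 with negative log2 fold changes. Of these, 454 were also called here with edgeR, each with the same sign. Across genes with a mean log2 CPM of at least 1, which are not independent replicates, Pearson's r between the log2 fold changes here and in the authors' deposited table was 0.9998. The authors' deposited table gave MAC3B a log2 fold change of 2.72.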

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

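The alternatives were chosen before the data were examined, except the introns above 0 in all columns, the scores relative to expression, the limit of 20 reads, the events with a mean of at least 50 reads, and all values of introns that differ by at least 4, which were chosen after seeing the data. The pseudocount of 0.01 was the planned main value, and it became an alternative when 1 was chosen in its place after seeing the data. No paired analysis was possible because the genotypes share only 1 replicate number, which is 1 by the sample titles and 3 by the column names of the count table. Without a filter on low counts 570 genes were higher and 520 lower, with more genes of few counts tested, and with a log2 fold change of at least 1 the counts were 88 and 20. Leaving out each library gave 84 to 887 higher and 51 to 961 lower genes. The other normalizations and filters and DESeq2 (270 higher, 237 lower) stayed within 1.5 times the 345 and 272. MAC3B stayed past the threshold under RLE, DESeq2 and each library left out, with log2 fold changes of 2.58 to 2.85, and MAC3A did not pass in any, at -0.01 to 0.03. For the other 51 named genes, 231 of 293 alternative values stayed on their side of the threshold, 60 lost the call, 2 gained it and 0 changed direction. Some genes had no adjusted p in DESeq2, so a call kept throughout means kept in every alternative that gave the gene a value. Of the 48 of these genes past the threshold, the call was lost by 25 without wild type replicate 1, 18 without wild type replicate 2, 6 without mutant replicate 1, 5 without mutant replicate 3 and 6 of 36 with an adjusted p in DESeq2, while 20 kept it throughout. Camera with an estimated correlation placed 0 lists higher and 0 lower and fry 1 and 0, and leaving out each library gave 4 to 8 higher lists and 2 lower lists. Limma on intron scores called 2 higher and 2 lower introns among those above 0 in all columns, and 0 to 7331 higher and 0 to 25 lower introns with each column left out. Introns that differ by at least 4 numbered 6221 higher and 4763 lower with a pseudocount of 0.1, 12323 and 9493 with 0.01, and 13464 and 10494 with 0.001, since a smaller pseudocount widens every difference from 0. They numbered 18 and 19 among introns above 0 in all columns, and 2346 to 4142 and 1366 to 2979 with each column left out. The shift of the score medians ran from 0.03 to 0.10 with each column left out. Of the authors' events, 239 were higher in group 1 with at least 20 reads in every library, 157 in group 1 and 213 in group 2 with at least 50 reads, and 220 and 241 with a difference of at least 0.1, each limit keeping fewer events. The odds ratios ran from 1.33 to 1.77 without passing, and the intron properties did not pass with one intron per gene. The edgeR and logit tests of inclusion counts, and their fits without each library, were not run because the groups are not named. For the other changes of call or count the cause was not tested. Depth limits genes near 1 CPM, where few counts stand behind each value, and intron scores, where coverage 1 read deep gives a score of 10.1 to 12.9.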

Other observations

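All tests in this part were chosen only after the results were seen, and the genes named here were chosen after their values were seen. Outside the lists, 6 of 42 genes annotated to nuclear transport rose and 0 fell. Beside AT1G59660, the Ran GTPase genes RAN-1 and RAN2 rose by 1.81 (SE 0.0769, n = 2 per genotype) and 0.95 (SE 0.0906) on the log2 scale, the exportin gene XPO1B by 1.498 (SE 0.122), the Ran import factor gene NTF2B by 1.29 (SE 0.0836) and XPO1A by 0.39 (SE 0.0778). Not among the 42 by their annotation, AT1G69680, the mRNA export factor gene RAE1 (2.02, SE 0.0884) and the Ran-binding gene SIRANBP (0.38, SE 0.0762) rose as well. RAN3 was at 0.10 (SE 0.0760) and AT1G10390, the homologue of AT1G59660, at 0.16 (SE 0.0770), and neither passed edgeR. The cytochrome P450 gene CYP82C2 rose from 19.7 ± 1.67 to 71.7 ± 2.06 CPM, and WAK1 (2.03, SE 0.372), ACD6 (1.56, SE 0.322), NAC103 (2.26, SE 0.538) and NAC044 (2.03, SE 0.465) were higher, while WAK1 stood at 10.2 CPM in mutant replicate 1 and 3.85 in mutant replicate 3. The myrosinase genes TGG2 and TGG1, whose products break down glucosinolates, fell by 0.83 (SE 0.0793) and 0.33 (SE 0.0860). The BTB and TAZ domain genes BT1 and BT2 fell by 0.87 (SE 0.0795) and 0.53 (SE 0.0742), and the squalene synthase gene SQS2 rose by 1.25 (SE 0.223).

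Some transcripts were close to present or absent by genotype. QQS, an orphan gene of starch metabolism, dropped 24.97-fold from 7.38 ± 0.819 to 0.284 ± 0.111 CPM. AT1G64795 had 0 counts in both wild-type libraries and 180 and 193 in the mutant, at least 54.7-fold higher against a floor of 3 counts per library, although 70.6% of its exon bases overlap ILA on the other strand. AT1G06957 had 18 and 23 counts in wild type and 0 in both mutant libraries, at least 7.73-fold lower against that floor. AT5G45990, on chromosome 5 like AT5G46070, rose by 4.14 (SE 0.507).

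Changed genes also lay beside each other more often than shuffled positions gave. Among the tested genes in chromosome order there were 28 adjacent pairs called in the same direction. In 2000 permutations of the calls over gene positions the mean was 9.48 and the highest value 19 (permutation p = 0.0005, the smallest that they can give). Untested genes between a pair were skipped, and a run such as SSR16, AT4G34630, SQS1 and SQS2 counts as several pairs. Some pairs overlap in position, such as AT1G28715 with AT1G28890, and the counting did not use strand. Without pairs that share an annotated product or whose proteins share at least 3 words of 5 residues, 17 remained (mean 8.77, highest value 18, permutation p = 0.00900), while pairs in opposite directions numbered 10 (mean 9.01, permutation p = 0.411). Examples of the 28 are AT5G46060 with AT5G46070, HA9 with RAE1, RAN-1 with RAN2, AT2G15880 with MEE14, BHLH38 with BHLH39, and SQS1 with SQS2. Apart from similar neighbours, no explanation for the adjacency was tested.

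The rise of these nuclear transport genes was weighed against shared reads and a general rise of the class. Reads moving between the near-identical RAN copies would leave their sum unchanged. RAN-1, RAN2 and RAN3 added up rose by 1.23 on the log2 scale (SE 0.0739), and by 1.14 to 1.31 with each library left out. This argues against moved reads as the source of the whole rise. It does not decide whether part of the RAN2 rise came from misplaced reads of RAN-1. A smaller rise across the class stays open, since the 42 genes had a median log2 fold change of 0.13 with quartiles of 0.02 and 0.27. As a set they passed camera with the preset correlation (p = 1.57e-06) and not with an estimated one (p = 0.177), which has little power here. The class was formed after its raised members were seen and includes them, so neither value decides whether the whole class rose. The data are consistent with a hypothesis that Ran and export genes respond to the mutant MAC3B or to its raised level, which the samples do not separate, and an effect of the transgene insertion in this line also stays open.

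The clock genes may reflect a phase nearer dawn in the mutant libraries. Among the clock genes that did not pass the threshold, the median log2 fold change of 9 dawn genes lay 0.37 above that of 11 day and evening genes (exact permutation p = 0.0284, two-sided), as this hypothesis requires. Over all 24 genes 12 of 12 dawn genes were above 0 and 10 of 12 day and evening genes below. A single aberrant mutant library is argued against, since the medians of these 12 and 12 genes differed by 0.46 without mutant replicate 1 (permutation p = 0.00352, two-sided) and by 0.40 without mutant replicate 3 (permutation p = 0.0229), over genes, which are not independent replicates. The labels give no time of harvest, so a difference in the hour of sampling stays open beside a changed clock, and neither was tested.

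The introns that differ by at least 4 between the genotypes are likely in large part replicate spread and columns listed at 0. A pairing of columns that mixes the genotypes gave at least 2234 such introns against 2336. Introns covered 5 to 10 reads deep in 1 column were listed at 0 in another column of the same genotype in 18.9% of cases, and across genotypes in 19.4%. Of these introns 3.90% lay in genes called in the same direction. Among the 20483 tested genes 345 were called higher and 272 lower, 3.01% for both directions together. The 3.90% thus lies above the share of tested genes called in a single direction, and whether this is an enrichment was not tested. In called genes 64 higher and 27 lower introns went with expression, and 17 higher and 13 lower introns went against it. The genes of the higher and lower introns had median log2 fold changes of 0.03 and -0.05. These small medians argue against changed expression as the main source. A genotype effect on single introns stays open, since limma had little power over the wider set in the simulation. Among the introns above 0 in all columns it called 2 higher and 2 lower, each in a gene whose expression had changed in the same direction. Relative to gene expression it called 0 introns. In simulated scores of the introns above 0 in all columns limma recovered only 1 of 66 shifts of 4, so those 0 calls decide little. Whether the 2 higher and 2 lower introns go beyond the expression changes of their genes therefore cannot be told here.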
